A study of Mus musculus with 9 samples.

How the data were processed

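Gene expression was measured by RNA sequencing in CD71+Ter119+ cells sorted from mouse spleen, with 3 wildtype, 3 Dhh heterozygous and 3 Dhh knockout libraries. The authors deposited 1 table of FPKM-type values for 20368 genes, with 1 column per library. The submitters' processing notes name TopHat, Picard, DESeq2 and the build mm10, without versions or roles. The annotation, the strandedness and whether reads were paired are not given in the sources used here, so FPKM and RPKM cannot be told apart. Overlapping genes, antisense genes and near-identical copies can share reads in such values.

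The unit was checked on the values. All 14147 genes above 0 in at least 2 libraries were whole multiples of a per-gene step, within 0.05 of a read. The library factors of these steps equalled median-of-ratios size factors over 11276 genes to 6 decimals. The deposited FPKM are therefore reads divided by a constant per gene and by a size factor, not by the library total. A composition shift between libraries can move such a factor. The recovered reads ranged from 7.05 to 14.23 M per library, and a count of 0 allows up to 3 reads, which covers counting error only. Ensembl identifiers were matched to GENCODE M21 on the same build for 20092 of the rows (98.6%), which gave the positions. 26 symbols that a spreadsheet had turned into dates were restored from it, and 180 rows had no symbol.

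Values were analysed as log2(FPKM + 1), so the fold changes of low genes are understated. Genes with at least 1 FPKM in at least 3 libraries were kept, 9543 in all. Limma 3.58.1 in R 4.3.3 fitted a mean per genotype over all 9 libraries (lmFit, and eBayes with a trend), and Benjamini-Hochberg adjusted p below 0.05 was the threshold in each of 3 2-sided contrasts. A second fit used the number of null alleles. Camera, with a preset correlation of 0.01, tested 35 of 38 lists with at least 5 tested members. The mitochondrial, stromal and endothelial, and Y-linked lists had too few tested members. Camera with an estimated correlation and fry were alternatives. Exact permutation of 3 against 3 libraries cannot give a p below 0.1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the recovery of reads and the figures.

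The design, the lists and the rule for named genes were fixed before the data were examined. The rule named Dhh and Hedgehog genes, called genes with groups that did not overlap, up to 4 called or 2 most abundant members of each list, the 10 lowest unadjusted p where fewer than 10 genes passed, 10 fixed genes (Gata1, Klf1, Tfrc, Hba-a1, Hbb-bs, Alas2, Epor, Kit, Bmp4 and Smad5) and the members of the sex-linked list. Genes outside it (Fos, C1qa, Cela1, Tuba1a, Dazap2, Tmem106c, Apobec3, Fam118a, Lars2, Mettl7a1 and Parvg) were chosen after their values were seen. The limma test was tried on simulated data for knockout versus wildtype with the covariance of the real residuals. It called 7.6% of genes changed 1.5-fold, 33.4% of those changed 2-fold, 73.2% at 4-fold and 83.4% at 8-fold, with 3.5% false calls. Each of the 10 simulations changed genes at all of these folds together, 500 genes per fold in all. Many changed genes ease the adjusted threshold, so these shares overstate the calls where few genes change. No pair of libraries agreed within sampling noise (lowest chi-square per degree of freedom 8.11 over 36 pairs).

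For the gene counts of each pair, 20 alternatives were fixed beforehand: quantile normalization, other filters and pseudocounts, no trend, the replicate number as a block, globin genes left out, other thresholds, only the libraries of a pair, and each library left out. 7 were added after seeing the data: voom on recovered reads, a depth term, 2 covariate fits, the joint omission of wildtype replicate 3 and knockout replicate 2, and 2 kinds of library quality weights. Depth sets were defined by recovered reads. The replicate numbers come from the labels, which name no shared litter, batch or day. The correlations of the deviations of same-numbered libraries from their group means (numbers 1, 2 and 3) were 0.20, 0.18 and 0.41 between knockout and heterozygous, all above 0.1, so the numbers were taken to pair these 2 groups. They were -0.57, 0.51 and 0.33 between knockout and wildtype. Between heterozygous and wildtype they were 0.13, 0.18 and 0. Wildtype libraries were not taken to pair with either group. No label states the pairing, and replicate 2 was the only shallower library in both the knockout and the heterozygous group. A count model on recovered reads was planned and not run, since a count test is not used on FPKM here, and voom was run in its place.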

Results

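RNA sequencing was carried out on erythroblasts sorted from the spleens of 4-week-old C57BL/6 mice that carried 0, 1 or 2 null alleles of Dhh, the gene for the secreted ligand Desert hedgehog. The sorted cells carried both CD71, the transferrin receptor, and Ter119, an antigen of the erythroid lineage. There were 3 wildtype, 3 heterozygous and 3 knockout libraries. The labels do not say whether each library came from its own mouse, so the p-values measure the spread between these libraries. The reads recovered from the deposited FPKM values (in units of 1e6, written M) ranged from 7.05 M in heterozygous replicate 2 to 14.23 M in heterozygous replicate 1. Between 8235 and 9553 genes per library were at or above 1 FPKM, and 9543 genes were tested.

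Dhh (ENSMUSG00000023000, chromosome 15, 98891152 to 98898540, mm10) was listed at 0 in 8 libraries and at 0.0267 FPKM in heterozygous replicate 1. It was listed at 0 in the wildtype libraries too, so its level does not check the genotype labels. Erythroid genes were abundant in every library. Gata1, a transcription factor required for red cell development, was at 219 ± 34.9 in wildtype, 198 ± 7.98 in heterozygous and 211 ± 34.3 in knockout libraries (FPKM, mean ± SD, n = 3 each). Klf1, which activates the adult beta-globin genes, was at 377 ± 50.5 in wildtype, 341 ± 16.2 in heterozygous and 368 ± 52.4 in knockout libraries. The adult globin genes took 2.52% to 5.06% of the summed FPKM.

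2 structures of the libraries ran across the genotypes, and they went together. The first was depth. Wildtype replicates 1 and 2, heterozygous replicate 2 and knockout replicate 2 had 7.05 to 9.66 M reads, and the other 5 libraries had 13.1 M or more. Adult globin genes took 4.14% or more of the FPKM in the 4 shallower libraries and 2.86% or less in the 5 deeper ones. The second was the level of markers of other blood cells. Cd74, an antigen presentation gene of B cells and myeloid cells, was at 751 FPKM in wildtype replicate 1 and 49.6 FPKM in wildtype replicate 3. C1qa, a complement gene of macrophages, was at 198 FPKM in knockout replicate 2 and 12.2 FPKM in wildtype replicate 3. The mean of the marker lists was 3.75 to 4.33 on the log2(FPKM + 1) scale in the 4 shallower libraries and 1.76 to 3.53 in the 5 deeper ones, so each shallower library lay above each deeper one. The first principal component held 62.2% of the variance and set wildtype replicate 3 apart from wildtype replicate 1 and knockout replicate 2.

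The first comparison asked what the loss of both Dhh alleles does in these erythroblasts. None of the erythroid genes named here passed the test between knockout and wildtype. Epor, the erythropoietin receptor, was at 236 ± 32.3 in wildtype, 234 ± 19.2 in heterozygous and 260.5 ± 50.9 in knockout libraries (FPKM, mean ± SD, n = 3 each). Tfrc, which encodes CD71, was at 477 ± 4.05 in wildtype, 444 ± 53.03 in heterozygous and 487 ± 124 in knockout libraries. For Hba-a1, Hbb-bs and Alas2 the SD within wildtype exceeded the difference of the means. Hba-a1 was at 2728 ± 595 in wildtype, 2346 ± 1151 in heterozygous and 2319 ± 650.2 in knockout libraries, Hbb-bs at 7269 ± 1661 in wildtype, 5740 ± 2812 in heterozygous and 5964 ± 1889 in knockout libraries, and Alas2, the first enzyme of heme synthesis in red cells, at 5846 ± 1579 in wildtype, 4445 ± 2610 in heterozygous and 4539 ± 1971 in knockout libraries. Kit, the stem cell factor receptor, was at 1.08 ± 0.224 in wildtype, 1.49 ± 0.719 in heterozygous and 1.54 ± 0.718 in knockout libraries. Smad5, a mediator of BMP signals, was at 1.62 ± 0.260 in wildtype, 1.66 ± 0.108 in heterozygous and 1.44 ± 0.338 in knockout libraries, and Bmp4 was listed at 0 in all libraries but wildtype replicate 3 (0.0375 FPKM). The log2 differences between knockout and wildtype were -0.06 ± 0.16 for Gata1, -0.04 ± 0.15 for Klf1, -0.0029 ± 0.19 for Tfrc, 0.13 ± 0.17 for Epor, -0.24 ± 0.33 for Hba-a1, -0.30 ± 0.35 for Hbb-bs, -0.41 ± 0.42 for Alas2, 0.26 ± 0.28 for Kit and -0.11 ± 0.17 for Smad5 (SE).

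**Figure D1:**
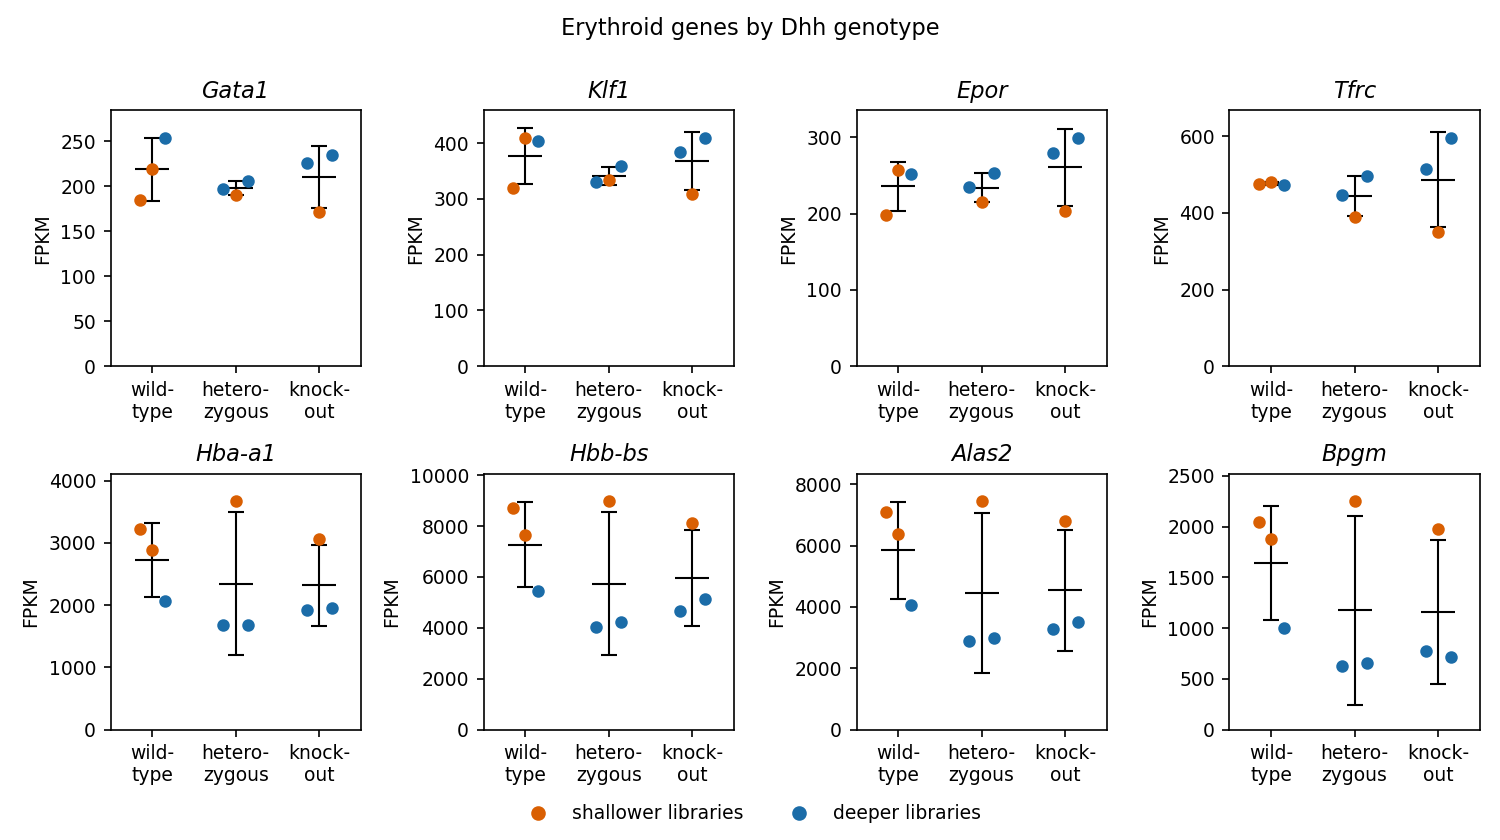
FPKM of 8 erythroid genes in each library (points) by Dhh genotype, with the mean and SD of 3 libraries as bars and the depth set as colour. Hba-a1, Hbb-bs, Alas2 and Bpgm separate by depth set within each genotype, for example Alas2 at 7458 FPKM in heterozygous replicate 2 and 2884 FPKM in heterozygous replicate 1.

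No gene passed the test between knockout and wildtype. The limma model called 0 of 9543 genes at an adjusted p below 0.05, and the lowest adjusted p was 0.9997. At an unadjusted p below 0.05 there were 43 genes, against 477 expected by chance. Voom on the recovered reads called 0 genes, with 38 at an unadjusted p below 0.05. The median 95% interval of a gene reached 0.42 to each side on the log2(FPKM + 1) scale. For 86.6% of the genes the interval lay within a 2-fold change on that scale, which understates the changes of low genes. The 10 genes with the lowest unadjusted p, given as log2 difference and SE, were Mettl7a3 (1.72 ± 0.35, unadjusted p = 0.000888), Mettl7a2+Methig1 (1.25 ± 0.33, unadjusted p = 0.00467), Fah (0.66 ± 0.18, unadjusted p = 0.0054), Smarcd1 (-0.51 ± 0.15, unadjusted p = 0.00853), Spryd7 (-0.49 ± 0.15, unadjusted p = 0.00983), Fabp5 (-0.53 ± 0.17, unadjusted p = 0.011), Itgb1bp2 (-0.51 ± 0.16, unadjusted p = 0.0115), Bloc1s1 (-0.58 ± 0.18, unadjusted p = 0.0117), Dynlrb1 (-0.40 ± 0.13, unadjusted p = 0.0119) and Ppp1r14a (0.92 ± 0.30, unadjusted p = 0.0127). Mettl7a3, with Mettl7a2 and Smarcd1, lies on the chromosome of Dhh. Mettl7a3 (chromosome 15, 100334929 to 100340375, mm10) was listed at 0 in the 3 wildtype libraries and was at 1.83, 1.98 and 3.24 FPKM in the knockout libraries. With wildtype at 0, its fitted difference depends on the pseudocount and is no bound, and related neighbouring genes can share its reads. Knockout and wildtype libraries did not overlap for 2.5% of genes, against 10% by chance. With depth as a term limma called 0 genes, with 208 at an unadjusted p below 0.05. This unadjusted count was 133 without wildtype replicate 1, 88 without wildtype replicate 2, 228 without wildtype replicate 3 and 252 without knockout replicate 2, and the adjusted count stayed at 0.

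Of the Hedgehog pathway list, 8 of 28 genes passed the expression filter, and 0 passed the test, over all genes or adjusted over the list alone. The most abundant were Csnk1a1, a kinase that phosphorylates Gli proteins, at 105 ± 16.2 in wildtype, 106 ± 6.56 in heterozygous and 103 ± 12.8 in knockout libraries (FPKM, mean ± SD, n = 3 each), and Spop, an adaptor for Gli degradation, at 76.2 ± 9.57 in wildtype, 67.0 ± 4.92 in heterozygous and 69.1 ± 3.84 in knockout libraries. Arrb2 was at 28.8 ± 17.8 in wildtype, 31.2 ± 2.78 in heterozygous and 30.3 ± 13.1 in knockout libraries and Prkaca at 18.1 ± 4.52 in wildtype, 19.2 ± 1.19 in heterozygous and 17.5 ± 0.235 in knockout libraries. Ptch1, the Hedgehog receptor, was at 2.73 ± 0.795 in wildtype, 2.71 ± 0.760 in heterozygous and 2.28 ± 0.738 in knockout libraries. The mean log2 difference of the list between knockout and wildtype was 0.01 and its median -0.04, which differ in sign (camera adjusted p = 0.843).

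Camera with its preset correlation called 6 of 35 lists between knockout and wildtype. The ribosomal proteins list was lower in knockout libraries for 77 of 80 genes, with a mean log2 difference of -0.15 (camera adjusted p = 6e-19, and adjusted p = 0.966 with an estimated correlation). The G1/S and DNA replication list was lower in knockout libraries for 31 of 34 genes, with a mean log2 difference of -0.09 (camera adjusted p = 0.019, and adjusted p = 0.966 with an estimated correlation). The immediate early and dissociation genes list was lower in knockout libraries for 15 of 22 genes, with a mean log2 difference of -0.21 (camera adjusted p = 0.019, and adjusted p = 0.966 with an estimated correlation). The Type I interferon response list was higher in knockout libraries for 21 of 28 genes, with a mean log2 difference of 0.14 (camera adjusted p = 0.019, and adjusted p = 0.966 with an estimated correlation). The late erythroid maturation genes list was lower in knockout libraries for 20 of 28 genes, with a mean log2 difference of -0.13 (camera adjusted p = 0.0308, and adjusted p = 0.966 with an estimated correlation). The B cell markers list was higher in knockout libraries for 17 of 17 genes, with a mean log2 difference of 0.35 (camera adjusted p = 0.0308, and adjusted p = 0.966 with an estimated correlation). The members that passed the gene test numbered 0 in every list of this comparison, over all genes and adjusted over the list alone. Fry called 0 lists (lowest adjusted p = 0.992). For each of the 6 lists, leaving out 1 library changed the sign of the mean relative to other genes or, for the late erythroid list, camera's direction alone. Without wildtype replicate 3, the G1/S and B cell lists turned to 0.19 and -0.43 relative to other genes, the interferon list to -0.09 and the ribosomal list to 0.03. Without knockout replicate 2 the G1/S list turned to 0.02. Without wildtype replicate 1, whose Fos level was 252 FPKM against 39.1 and 30.8 in the other wildtype libraries, the immediate early list turned to 0.40 and the late erythroid list kept a negative mean (-0.07) with camera's direction up. With the leukocyte marker mean as a covariate, 3 of the 6 lists stayed called, and the G1/S, interferon and B cell lists did not. That mean includes the B cell markers themselves, so the loss of their call is no separate evidence. With depth as a term 5 of the 6 stayed called, and the late erythroid list did not (camera adjusted p = 0.531). Without wildtype replicate 3 and knockout replicate 2 together, 0 of the 6 stayed called in the same direction. The number of lists called was 14 without wildtype replicate 1, 10 without wildtype replicate 2, 16 without wildtype replicate 3 and 10 without knockout replicate 3. Further calls were lost when 1 library was left out. Without wildtype replicate 1, the camera adjusted p was 0.105 for Type I interferon. Without wildtype replicate 2, the camera adjusted p was 0.372 for late erythroid. Without wildtype replicate 3, the camera adjusted p was 0.801 for ribosomal proteins. Without knockout replicate 1, the camera adjusted p was 0.204 for immediate early. Without knockout replicate 2, the camera adjusted p was 0.494 for late erythroid, 0.494 for Type I interferon, 0.409 for immediate early and 0.99 for B cell.

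**Figure D2:**
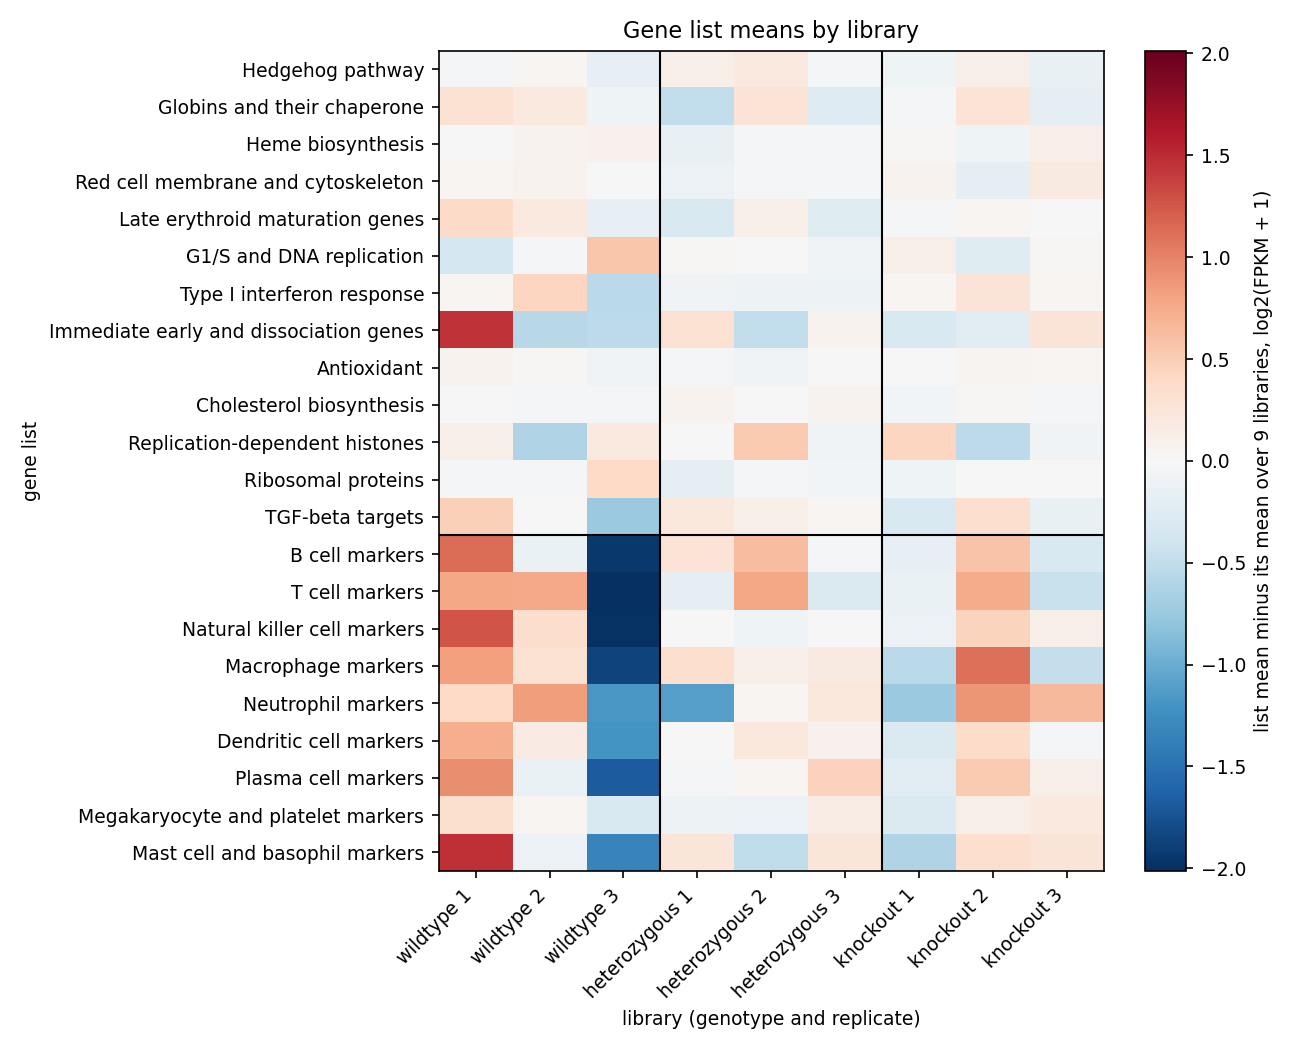
Mean log2(FPKM + 1) of each gene list in each library, minus the list's mean over the 9 libraries, for lists called in any comparison (above the line) and markers of other blood cells (below it). The marker lists are lowest in wildtype replicate 3, where the T cell list was at 0.32 against 3.11 in wildtype replicate 1.

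The most abundant members of the called lists are given as FPKM (mean ± SD, n = 3). Among ribosomal proteins, these were Rplp0 at 1151 ± 272 in wildtype and 969 ± 83.7 in knockout libraries and Rpl41 at 1116 ± 114.9 in wildtype and 987 ± 47.8 in knockout libraries. G1/S genes were led by Pcna at 686 ± 179 in wildtype and 617 ± 66.2 in knockout libraries and Rrm2 at 584 ± 99.7 in wildtype and 579 ± 72.0 in knockout libraries. Immediate early and dissociation genes were led by Ppp1r15a at 620.1 ± 76.1 in wildtype and 585 ± 129.7 in knockout libraries and Btg2 at 151 ± 8.85 in wildtype and 137 ± 25.1 in knockout libraries. Interferon response genes were led by Rsad2 at 719 ± 213 in wildtype and 634 ± 102 in knockout libraries and Isg15 at 631 ± 259 in wildtype and 600.4 ± 140 in knockout libraries. Late erythroid genes were led by Ube2l6 at 1727 ± 471 in wildtype and 1362 ± 563 in knockout libraries and Bpgm at 1640 ± 562 in wildtype and 1153 ± 709 in knockout libraries. B cell markers were led by Cd74 at 357 ± 359 in wildtype and 358 ± 165 in knockout libraries and H2-Aa at 124 ± 129 in wildtype and 109 ± 45.3 in knockout libraries. The list directions use means of log2(FPKM + 1). H2-Aa therefore counted as higher in knockout libraries although its mean FPKM was lower.

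The remaining lists were not called between knockout and wildtype, and their levels are given as FPKM (mean ± SD, n = 3). The erythroid transcription factors list (mean log2 difference -0.0032, camera adjusted p = 0.921) was led by E2f4 at 370.5 ± 52.5 in wildtype and 359.7 ± 67.9 in knockout libraries and Klf1 at 377 ± 50.5 in wildtype and 368 ± 52.4 in knockout libraries. The globins and their chaperone list (mean log2 difference -0.13, camera adjusted p = 0.696) was led by Hbb-bs at 7269 ± 1661 in wildtype and 5964 ± 1889 in knockout libraries and Hbb-bt at 3594 ± 857 in wildtype and 2919 ± 1026 in knockout libraries. The heme biosynthesis list (mean log2 difference -0.03, camera adjusted p = 0.886) was led by Alas2 at 5846 ± 1579 in wildtype and 4539 ± 1971 in knockout libraries. The iron uptake and handling list (mean log2 difference -0.03, camera adjusted p = 0.422) was led by Fth1 at 2403 ± 65.1 in wildtype and 2257 ± 105 in knockout libraries and Ftl1 at 1707 ± 330.5 in wildtype and 1622 ± 588 in knockout libraries. The red cell membrane and cytoskeleton list (mean log2 difference -0.01, camera adjusted p = 0.921) was led by Slc4a1 at 3479 ± 188 in wildtype and 3273 ± 297 in knockout libraries. The early erythroid progenitor genes list (mean log2 difference -0.02, camera adjusted p = 0.921) was led by Car1 at 279 ± 120.5 in wildtype and 232 ± 40.1 in knockout libraries and Npm1 at 113 ± 16.5 in wildtype and 108 ± 17.1 in knockout libraries. The erythropoietin and JAK-STAT5 signalling list (mean log2 difference 0.05, camera adjusted p = 0.709) was led by Tfrc at 477 ± 4.05 in wildtype and 487 ± 124 in knockout libraries and Bcl2l1 at 295 ± 62.0 in wildtype and 285 ± 25.9 in knockout libraries. The BMP and stress erythropoiesis list (mean log2 difference -0.04, camera adjusted p = 0.8) was led by Id2 at 21.4 ± 19.1 in wildtype and 17.1 ± 7.74 in knockout libraries and Nr3c1 at 8.36 ± 0.642 in wildtype and 8.17 ± 0.990 in knockout libraries. Mean and median of the heme and BMP lists differed in sign.

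The remaining cell cycle, stress and metabolic lists likewise gave no call between knockout and wildtype. The G2/M and mitosis list (mean log2 difference 0.02, camera adjusted p = 0.921) was led by Ube2c at 978 ± 58.7 in wildtype and 928 ± 48.7 in knockout libraries and Mki67 at 585 ± 27.6 in wildtype and 571 ± 90.3 in knockout libraries. The p53 targets list (mean log2 difference -0.07, camera adjusted p = 0.244) was led by Btg2 at 151 ± 8.85 in wildtype and 137 ± 25.1 in knockout libraries and Sesn1 at 55.6 ± 8.37 in wildtype and 56.7 ± 15.2 in knockout libraries. The apoptosis regulators list (mean log2 difference -0.04, camera adjusted p = 0.244) was led by Bcl2l1 at 295 ± 62.0 in wildtype and 285 ± 25.9 in knockout libraries and Mcl1 at 50.7 ± 8.97 in wildtype and 51.9 ± 3.05 in knockout libraries. The unfolded protein and integrated stress response list (mean log2 difference -0.03, camera adjusted p = 0.921) was led by Ppp1r15a at 620.1 ± 76.1 in wildtype and 585 ± 129.7 in knockout libraries and Eif2ak1 at 545 ± 45.3 in wildtype and 552 ± 118 in knockout libraries. The heat shock list (mean log2 difference 0.09, camera adjusted p = 0.696) was led by Hspa8 at 410 ± 65.8 in wildtype and 347 ± 5.39 in knockout libraries and Hsp90aa1 at 222 ± 7.28 in wildtype and 212 ± 8.65 in knockout libraries. The antioxidant list (mean log2 difference 0.02, camera adjusted p = 0.921) was led by Prdx2 at 2876 ± 91.0 in wildtype and 2681 ± 174 in knockout libraries and Gpx1 at 2236 ± 439.8 in wildtype and 1890 ± 344 in knockout libraries. The glycolysis and bisphosphoglycerate list (mean log2 difference 0.01, camera adjusted p = 0.937) was led by Bpgm at 1640 ± 562 in wildtype and 1153 ± 709 in knockout libraries and Gapdh at 233 ± 38.7 in wildtype and 204 ± 27.0 in knockout libraries. The cholesterol biosynthesis list (mean log2 difference -0.0004, camera adjusted p = 0.921) was led by Fdft1 at 25.6 ± 4.21 in wildtype and 29.2 ± 5.26 in knockout libraries and Srebf2 at 26.2 ± 5.99 in wildtype and 22.9 ± 0.578 in knockout libraries. The replication-dependent histones list (mean log2 difference 0.04, camera adjusted p = 0.843) was led by Hist1h2bc at 68.1 ± 24.5 in wildtype and 55.8 ± 17.2 in knockout libraries and Hist1h2bg at 62.9 ± 38.9 in wildtype and 41.4 ± 20.4 in knockout libraries. Mean, median or test differed in sign for the unfolded protein, heat shock, glycolysis and cholesterol lists.

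Signalling targets and markers of other blood cells were measured in the same comparison. The Wnt pathway targets list (mean log2 difference 0.11, camera adjusted p = 0.709) was led by Ctnnb1 at 53.6 ± 8.29 in wildtype and 57.8 ± 2.78 in knockout libraries and Tcf7 at 9.94 ± 8.50 in wildtype and 8.66 ± 5.67 in knockout libraries. The Notch pathway list (mean log2 difference 0.02, camera adjusted p = 0.921) was led by Maml1 at 5.72 ± 0.391 in wildtype and 5.87 ± 1.10 in knockout libraries and Notch2 at 5.25 ± 2.03 in wildtype and 5.21 ± 1.84 in knockout libraries. The TGF-beta targets list (mean log2 difference 0.05, camera adjusted p = 0.709) was led by Tgfb1 at 42.1 ± 9.86 in wildtype and 44.97 ± 7.09 in knockout libraries and Tgfbr2 at 5.10 ± 4.38 in wildtype and 4.63 ± 2.71 in knockout libraries. The plasma cell markers list (mean log2 difference 0.43, camera adjusted p = 0.0995) was led by Jchain at 34.3 ± 38.4 in wildtype and 30.5 ± 14.98 in knockout libraries and Xbp1 at 14.1 ± 6.13 in wildtype and 13.7 ± 4.13 in knockout libraries. The T cell markers list (mean log2 difference 0.21, camera adjusted p = 0.423) was led by Lck at 17.3 ± 7.95 in wildtype and 16.1 ± 5.01 in knockout libraries and Lat at 9.83 ± 8.28 in wildtype and 10.8 ± 5.98 in knockout libraries. The natural killer cell markers list (mean log2 difference 0.27, camera adjusted p = 0.244) was led by Ccl5 at 49.7 ± 45.6 in wildtype and 50.8 ± 9.999 in knockout libraries and Gzma at 33.5 ± 35.0 in wildtype and 24.8 ± 5.62 in knockout libraries. The macrophage markers list (mean log2 difference 0.27, camera adjusted p = 0.0724) was led by Ctsb at 415 ± 78.0 in wildtype and 390.2 ± 54.8 in knockout libraries and Ctsd at 279.6 ± 33.7 in wildtype and 278 ± 24.6 in knockout libraries. The neutrophil markers list (mean log2 difference 0.25, camera adjusted p = 0.0995) was led by S100a9 at 344 ± 212 in wildtype and 358 ± 176 in knockout libraries and S100a8 at 224 ± 136 in wildtype and 245 ± 124 in knockout libraries. The dendritic cell markers list (mean log2 difference 0.11, camera adjusted p = 0.705) was led by Bst2 at 31.1 ± 15.9 in wildtype and 35.0 ± 8.27 in knockout libraries and Irf8 at 12.6 ± 10.04 in wildtype and 11.8 ± 5.24 in knockout libraries. The megakaryocyte and platelet markers list (mean log2 difference -0.02, camera adjusted p = 0.921) was led by Gp9 at 26.1 ± 6.24 in wildtype and 28.2 ± 7.91 in knockout libraries and Itga2b at 10.4 ± 3.58 in wildtype and 14.9 ± 3.77 in knockout libraries. The mast cell and basophil markers list (mean log2 difference -0.01, camera adjusted p = 0.921) was led by Ccl3 at 55.3 ± 85.1 in wildtype and 25.1 ± 15.6 in knockout libraries and Prss34 at 14.4 ± 13.8 in wildtype and 11.6 ± 9.99 in knockout libraries. Test and mean differed in sign for the Notch and megakaryocyte lists.

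The comparison of heterozygous with wildtype libraries asked whether loss of 1 allele changes expression. Camera's lowest p-values lay in ribosomal protein and late erythroid genes, which had lower means in heterozygous libraries, and no list was called with an estimated correlation. Rpl41 was at 1116 ± 114.9 in wildtype, 835 ± 66.1 in heterozygous and 987 ± 47.8 in knockout libraries (FPKM, mean ± SD, n = 3 each) and Rplp0 at 1151 ± 272 in wildtype, 935 ± 134 in heterozygous and 969 ± 83.7 in knockout libraries. Hbq1b, a theta-globin gene, was at 220.5 ± 21.3 in wildtype, 160.5 ± 2.70 in heterozygous and 209.6 ± 5.51 in knockout libraries. Uqcrh and Cox7b, subunits of the mitochondrial respiratory chain, were at 322 ± 31.6 in wildtype, 236 ± 12.5 in heterozygous and 276 ± 8.43 in knockout libraries and at 114 ± 6.40 in wildtype, 81.6 ± 8.67 in heterozygous and 101 ± 16.5 in knockout libraries. No gene passed the test, as limma called 0 of 9543 genes at an adjusted p below 0.05, and the lowest adjusted p was 0.9999. At an unadjusted p below 0.05 there were 113 genes, against 477 expected by chance. Voom called 0, with 91 at an unadjusted p below 0.05. Of those below 0.05 in limma, 98 were lower and 15 higher in heterozygous libraries. The 10 lowest, as log2 difference and SE, were Hbq1b (-0.45 ± 0.11, unadjusted p = 0.00216), Uqcrh (-0.44 ± 0.11, unadjusted p = 0.00343), Commd9 (-0.59 ± 0.16, unadjusted p = 0.00506), Bbc3 (-0.49 ± 0.14, unadjusted p = 0.00568), Cox7b (-0.48 ± 0.14, unadjusted p = 0.00717), Selk (-0.54 ± 0.16, unadjusted p = 0.00804), Rpl41 (-0.42 ± 0.12, unadjusted p = 0.00827), Snrnp27 (-0.40 ± 0.12, unadjusted p = 0.0107), Grcc10 (-0.44 ± 0.14, unadjusted p = 0.0108) and Supt4a (-0.44 ± 0.14, unadjusted p = 0.0108). Libraries of the pair did not overlap for 4.4% of genes, against 10% by chance. With depth as a term limma called 0 genes, with 662 at an unadjusted p below 0.05. This unadjusted count was 354 without wildtype replicate 1, 293 without wildtype replicate 3 and 62 without heterozygous replicate 1, and the adjusted count stayed at 0.

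Camera called 9 of 35 lists between heterozygous and wildtype. The ribosomal proteins list was lower in heterozygous libraries for 76 of 80 genes, with a mean log2 difference of -0.21 (camera adjusted p = 8.63e-26, and adjusted p = 0.658 with an estimated correlation). Its mean was 8.66 in wildtype replicate 3 and 8.24 in wildtype replicates 1 and 2. Leaving out single libraries kept the call, with a mean relative to other genes from -0.34 to -0.04. The late erythroid maturation genes list was lower in heterozygous libraries for 27 of 28 genes, with a mean log2 difference of -0.28 (camera adjusted p = 6.19e-08, and adjusted p = 0.658 with an estimated correlation). The B cell markers list was higher in heterozygous libraries for 17 of 17 genes, with a mean log2 difference of 0.61 (camera adjusted p = 6.47e-05, and adjusted p = 0.764 with an estimated correlation). The replication-dependent histones list was higher in heterozygous libraries for 34 of 50 genes, with a mean log2 difference of 0.25 (camera adjusted p = 0.00013, and adjusted p = 0.764 with an estimated correlation). The macrophage markers list was higher in heterozygous libraries for 25 of 28 genes, with a mean log2 difference of 0.46 (camera adjusted p = 0.00196, and adjusted p = 0.866 with an estimated correlation). The globins and their chaperone list was lower in heterozygous libraries for 8 of 9 genes, with a mean log2 difference of -0.30 (camera adjusted p = 0.00524, and adjusted p = 0.658 with an estimated correlation). The heme biosynthesis list was lower in heterozygous libraries for 18 of 20 genes, with a mean log2 difference of -0.13 (camera adjusted p = 0.0103, and adjusted p = 0.743 with an estimated correlation). The red cell membrane and cytoskeleton list was lower in heterozygous libraries for 22 of 27 genes, with a mean log2 difference of -0.08 (camera adjusted p = 0.0322, and adjusted p = 0.866 with an estimated correlation). The TGF-beta targets list was higher in heterozygous libraries for 7 of 8 genes, with a mean log2 difference of 0.20 (camera adjusted p = 0.0477, and adjusted p = 0.764 with an estimated correlation). Over all genes 0 list members passed, and adjusted over the list alone 1 did, Hbq1b in the list of globins and their chaperone. Of the 26 other lists, the lowest camera adjusted p was 0.0604, for immediate early and dissociation genes. Fry called 0 lists (lowest adjusted p = 0.967). Without wildtype replicate 3, the B cell, macrophage and TGF-beta lists turned to -0.17, -0.32 and -0.09 relative to other genes, and without wildtype replicate 2 the histone list turned to -0.03. Over genes with at least 10 FPKM in 3 libraries, the histone list was called in the opposite direction, at -0.35. The count was 15 without wildtype replicate 1 and 19 without wildtype replicate 3. Of the wildtype libraries 2 were shallower and of the heterozygous ones 1, and the late erythroid list was at 8.42 and 8.23 against 8.15 among the shallower libraries, and at 7.86 against 7.73 and 7.79 among the deeper ones. With the depth set as a term over all 9 libraries, the late erythroid list stayed lower (camera adjusted p = 0.000282), 7 of the 9 lists stayed called, and the globin and histone lists did not (camera adjusted p = 0.0847 and 0.165). With a filter of 10 FPKM 5 of the 9 stayed called, and the histone list turned to -0.35. Mean, median or test differed in sign for the erythroid transcription factor, apoptosis, glycolysis, natural killer and megakaryocyte lists. Further calls were lost when 1 library was left out. Without wildtype replicate 1, the camera adjusted p was 0.173 for globins, 0.159 for red cell membrane and 0.0622 for late erythroid. Without wildtype replicate 2, the camera adjusted p was 0.0524 for globins, 0.0598 for heme, 0.198 for red cell membrane and 0.0534 for TGF-beta. Without wildtype replicate 3, the camera adjusted p was 0.181 for heme. Without heterozygous replicate 1, the camera adjusted p was 0.179 for globins, 0.0895 for heme, 0.179 for red cell membrane and 0.179 for TGF-beta. Without heterozygous replicate 2, the camera adjusted p was 0.305 for histones. Without knockout replicate 2, the camera adjusted p was 0.0506 for TGF-beta. Without knockout replicate 3, the camera adjusted p was 0.054 for TGF-beta.

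The comparison of knockout with heterozygous libraries asked whether loss of the second allele changes expression further. Kdm6a, an X-linked histone demethylase, was at 34.7 ± 2.75 in wildtype, 31.2 ± 3.25 in heterozygous and 44.8 ± 2.57 in knockout libraries (FPKM, mean ± SD, n = 3 each). Trappc2l, a vesicle transport gene, was at 25.2 ± 1.90 in wildtype, 18.2 ± 2.04 in heterozygous and 29.3 ± 5.40 in knockout libraries. Isg15 and Rsad2, genes induced by interferon, were at 631 ± 259 in wildtype, 483 ± 112 in heterozygous and 600.4 ± 140 in knockout libraries and at 719 ± 213 in wildtype, 573 ± 184 in heterozygous and 634 ± 102 in knockout libraries. S100a8 and S100a9, abundant in neutrophils, were at 224 ± 136 in wildtype, 138 ± 63.7 in heterozygous and 245 ± 124 in knockout libraries and at 344 ± 212 in wildtype, 210.3 ± 94.7 in heterozygous and 358 ± 176 in knockout libraries. No gene passed, as limma called 0 of 9543 genes at an adjusted p below 0.05, and the lowest adjusted p was 0.9996. At an unadjusted p below 0.05 there were 56 genes, against 477 expected by chance. Voom called 0, with 53 at an unadjusted p below 0.05. The 10 lowest, as log2 difference and SE, were Trappc2l (0.65 ± 0.15, unadjusted p = 0.00216), Kdm6a (0.51 ± 0.12, unadjusted p = 0.00218), Srrd (-0.82 ± 0.21, unadjusted p = 0.00397), Hbq1b (0.38 ± 0.11, unadjusted p = 0.00578), Rsph3a (0.56 ± 0.16, unadjusted p = 0.00637), Npff (-0.96 ± 0.28, unadjusted p = 0.0073), Cklf (0.55 ± 0.16, unadjusted p = 0.00891), Trim12a (0.44 ± 0.14, unadjusted p = 0.0116), Dnd1 (0.44 ± 0.15, unadjusted p = 0.014) and Supt3 (0.44 ± 0.15, unadjusted p = 0.0147). Libraries of the pair did not overlap for 4.5% of genes, against 10% by chance. With depth as a term limma called 0 genes, with 146 at an unadjusted p below 0.05. This unadjusted count was 106 without wildtype replicate 3, 32 without heterozygous replicate 2, 499 without knockout replicate 2 and 29 without knockout replicate 3, and the adjusted count stayed at 0.

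Camera called 12 of 35 lists between knockout and heterozygous. The Type I interferon response list was higher in knockout libraries for 22 of 28 genes, with a mean log2 difference of 0.20 (camera adjusted p = 9.32e-06, and adjusted p = 0.64 with an estimated correlation). The replication-dependent histones list was lower in knockout libraries for 36 of 50 genes, with a mean log2 difference of -0.21 (camera adjusted p = 0.000193, and adjusted p = 0.963 with an estimated correlation). The neutrophil markers list was higher in knockout libraries for 18 of 20 genes, with a mean log2 difference of 0.56 (camera adjusted p = 0.000193, and adjusted p = 0.963 with an estimated correlation). The late erythroid maturation genes list was higher in knockout libraries for 26 of 28 genes, with a mean log2 difference of 0.15 (camera adjusted p = 0.000633, and adjusted p = 0.64 with an estimated correlation). The ribosomal proteins list was higher in knockout libraries for 65 of 80 genes, with a mean log2 difference of 0.07 (camera adjusted p = 0.00307, and adjusted p = 0.992 with an estimated correlation). The heme biosynthesis list was higher in knockout libraries for 17 of 20 genes, with a mean log2 difference of 0.10 (camera adjusted p = 0.0207, and adjusted p = 0.64 with an estimated correlation). The red cell membrane and cytoskeleton list was higher in knockout libraries for 24 of 27 genes, with a mean log2 difference of 0.07 (camera adjusted p = 0.0298, and adjusted p = 0.992 with an estimated correlation). The Hedgehog pathway list was lower in knockout libraries for 7 of 8 genes, with a mean log2 difference of -0.14 (camera adjusted p = 0.0298, and adjusted p = 0.466 with an estimated correlation). The globins and their chaperone list was higher in knockout libraries for 8 of 9 genes, with a mean log2 difference of 0.18 (camera adjusted p = 0.0298, and adjusted p = 0.64 with an estimated correlation). The cholesterol biosynthesis list was lower in knockout libraries for 16 of 23 genes, with a mean log2 difference of -0.07 (camera adjusted p = 0.0298, and adjusted p = 0.466 with an estimated correlation). The B cell markers list was lower in knockout libraries for 16 of 17 genes, with a mean log2 difference of -0.26 (camera adjusted p = 0.0474, and adjusted p = 0.992 with an estimated correlation). The antioxidant list was higher in knockout libraries for 17 of 21 genes, with a mean log2 difference of 0.06 (camera adjusted p = 0.0497, and adjusted p = 0.466 with an estimated correlation). In these lists 0 members passed over all genes and 0 adjusted over the list alone. Of the 23 other lists, the lowest camera adjusted p was 0.109, for the unfolded protein and integrated stress response. Fry called 0 lists (lowest adjusted p = 0.535). The count fell to 2 without heterozygous replicate 1, 7 without knockout replicate 1, 7 without knockout replicate 2 and 6 without knockout replicate 3. The histone list turned to 0.06 without knockout replicate 2 and the red cell membrane list to -0.01 without knockout replicate 3. With a filter of 10 FPKM, fixed beforehand, only 3 of the 12 stayed called (late erythroid, interferon and neutrophil). The histone list then turned to 0.07, and the camera adjusted p was 0.137 for Hedgehog, 0.178 for globin, 0.101 for heme, 0.137 for red cell membrane, 0.231 for antioxidant, 0.137 for cholesterol, 0.137 for ribosomal and 0.137 for B cell. The depth term left 12 of the 12 called. Mean, median or test differed in sign for the iron and mast cell lists. Further calls were lost when 1 library was left out. Without wildtype replicate 1, the camera adjusted p was 0.0582 for antioxidant. Without wildtype replicate 2, the camera adjusted p was 0.0608 for antioxidant and 0.0543 for B cell. Without heterozygous replicate 1, the camera adjusted p was 0.188 for Hedgehog, 0.575 for globins, 0.212 for heme, 0.337 for red cell membrane, 0.194 for late erythroid, 0.194 for antioxidant, 0.194 for cholesterol, 0.593 for ribosomal proteins, 0.188 for B cell and 0.575 for neutrophil. Without heterozygous replicate 2, the camera adjusted p was 0.197 for Hedgehog, 0.129 for antioxidant, 0.65 for histones and 0.555 for B cell. Without heterozygous replicate 3, the camera adjusted p was 0.12 for globins, 0.0981 for late erythroid, 0.0673 for antioxidant and 0.16 for cholesterol. Without knockout replicate 1, the camera adjusted p was 0.0718 for Hedgehog, 0.0718 for heme, 0.339 for red cell membrane, 0.08 for antioxidant, 0.08 for cholesterol and 0.324 for B cell. Without knockout replicate 2, the camera adjusted p was 0.0837 for Hedgehog, 0.618 for globins, 0.119 for Type I interferon, 0.197 for antioxidant, 0.119 for cholesterol, 0.487 for ribosomal proteins and 0.687 for neutrophil. Without knockout replicate 3, the camera adjusted p was 0.245 for Hedgehog, 0.534 for heme, 0.203 for antioxidant, 0.148 for cholesterol and 0.651 for B cell.

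Across the 3 genotypes, the slope of log2(FPKM + 1) per null allele was fitted over all 9 libraries. Mettl7a3, Mettl7a2 and Fah, an enzyme of tyrosine breakdown, had the lowest unadjusted p. The limma fit called 0 of 9543 genes at an adjusted p below 0.05, and the lowest adjusted p was 0.9997. At an unadjusted p below 0.05 there were 53 genes, against 477 expected by chance. Voom called 0, with 55 at an unadjusted p below 0.05. The slopes per allele and SE were Mettl7a3 (0.86 ± 0.17, unadjusted p = 0.000419), Mettl7a2+Methig1 (0.62 ± 0.16, unadjusted p = 0.00265), Fah (0.33 ± 0.09, unadjusted p = 0.00297), Itgb1bp2 (-0.25 ± 0.07, unadjusted p = 0.00661), Smarcd1 (-0.26 ± 0.08, unadjusted p = 0.00669), Dynlrb1 (-0.20 ± 0.06, unadjusted p = 0.00724), Fabp5 (-0.27 ± 0.08, unadjusted p = 0.00745), Tmem161b (-0.22 ± 0.07, unadjusted p = 0.0102), Spryd7 (-0.24 ± 0.08, unadjusted p = 0.0114) and Gcsh (0.38 ± 0.12, unadjusted p = 0.0122). This unadjusted count was 121 without wildtype replicate 1, 88 without wildtype replicate 2, 240 without wildtype replicate 3 and 206 without knockout replicate 2, and the adjusted count stayed at 0.

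**Figure D3:**
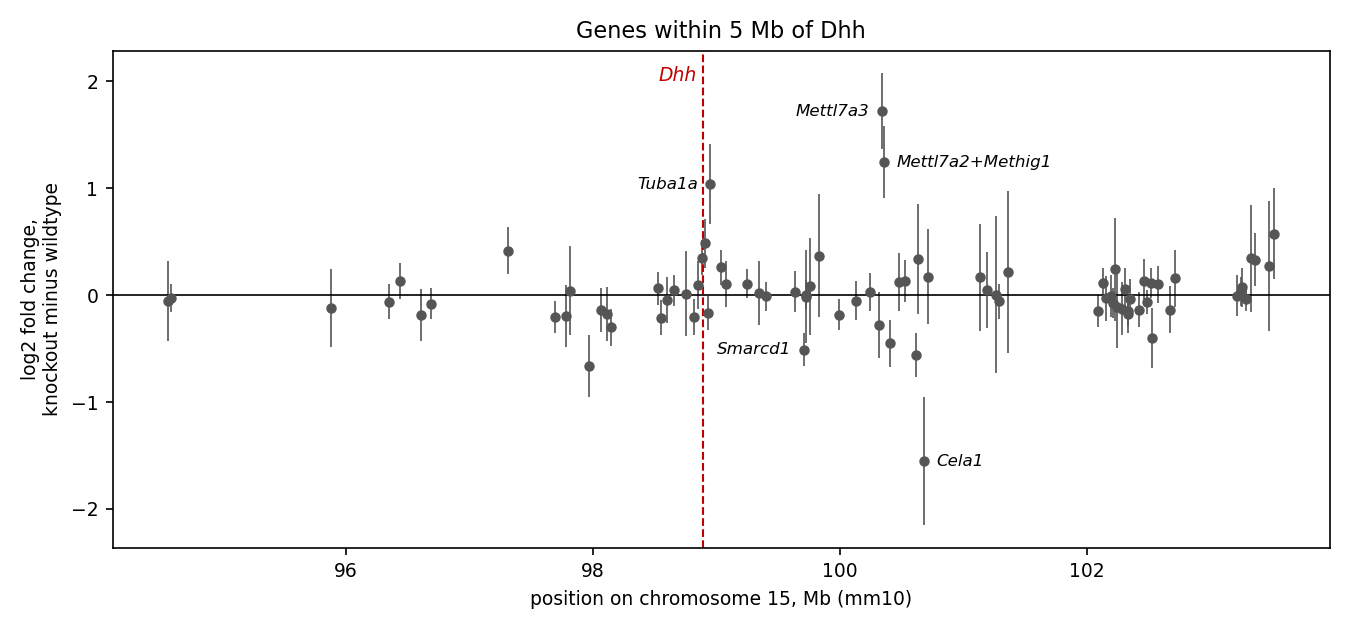
Log2 fold change between knockout and wildtype (points) with its SE (bars) for the tested genes within 5 Mb of Dhh on chromosome 15, by position in Mb on mm10, with Dhh as a dashed line. Mettl7a3 lies highest at 1.72 and Cela1 lowest at -1.55, and neither passed the test.

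The knockout and heterozygous fold changes against the same wildtype libraries were set beside each other across the 9543 genes, which are not independent replicates. Pearson's r was 0.64. In 1000 simulations of unchanged groups that shared the controls, r had a mean of 0.44, a median of 0.58 and a 95% range of -0.70 to 0.97. The covariance was 0.0223 against a simulated mean of 0.0467, a difference of -0.0243. Without knockout replicate 2, r was 0.14. The observed r lay inside the simulated range, and 45.9% of the simulations reached it.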

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

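The depth, covariate, voom, quality weight and joint omission settings were chosen after seeing the data. The gene counts, 0 in each pair and 0 for the allele number, stayed at 0 under the alternatives fixed before the data were examined, 20 for each pair and 19 for the allele number, where the libraries of a pair alone cannot be used. Of 7 alternatives chosen after seeing the data, 5 also gave 0 in all comparisons. Limma's REML library weights gave 1910, 739 and 2363 genes (knockout versus wildtype, heterozygous versus wildtype, allele number) and 0 between knockout and heterozygous. Those weights did not converge and gave wildtype replicate 2 a weight of 42.86 and the other wildtype libraries 0.26 and 0.12, so that 1 library stood for the wildtype. Limma's gene by gene weights called 0 genes in all 4, with 2122, 886, 1731 and 1995 at an unadjusted p below 0.05 (knockout versus wildtype, heterozygous versus wildtype, knockout versus heterozygous, allele number). Leaving out wildtype replicate 3 and knockout replicate 2 together gave 1 gene for the allele number (Parvg) and 0 in the pairs, with 2097 genes at an unadjusted p below 0.05 between knockout and wildtype. That pair was picked after seeing the values, and the other 8 pairs of 1 wildtype and 1 knockout library gave 56 to 324.

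The counts of lists (6, 9 and 12 in the order knockout versus wildtype, heterozygous versus wildtype, knockout versus heterozygous) became 0, 0 and 0 with an estimated correlation, 0, 0 and 0 by directional fry and 0, 0 and 0 by mixed fry. At 10 FPKM the knockout versus heterozygous count was 4. With depth as a term the first 2 counts were 13 and 14, and without the 2 libraries above 13 and 18. With the leukocyte marker mean as a covariate they were 4, 10 and 14, and that mean includes the members of the B cell, macrophage and neutrophil lists. Of the lists called at first, 5, 7 and 12 stayed called in the same direction with depth, 3, 7 and 11 with the marker mean and 0, 5 and 4 without the 2 libraries. Leaving out single libraries gave 5 to 16, 7 to 19 and 2 to 15 lists, and an r of fold changes from 0.14 to 0.89. Camera's direction changed for the lists below, given with their mean relative to other genes, which kept its sign for the late erythroid list. Without wildtype replicate 1, -0.0661 for Late erythroid (knockout versus wildtype), 0.40 for Immediate early (knockout versus wildtype). Without wildtype replicate 3, 0.19 for G1/S (knockout versus wildtype), -0.0864 for Type I interferon (knockout versus wildtype), -0.43 for B cell markers (knockout versus wildtype), -0.0931 for TGF-beta targets (heterozygous versus wildtype), -0.17 for B cell markers (heterozygous versus wildtype), -0.32 for Macrophage markers (heterozygous versus wildtype). Without knockout replicate 2, 0.0184 for G1/S (knockout versus wildtype), 0.055 for histones (knockout versus heterozygous). Leaving out 2 libraries that stand apart, 0.32 for G1/S (knockout versus wildtype), -0.14 for Type I interferon (knockout versus wildtype), -0.68 for B cell markers (knockout versus wildtype), -0.0931 for TGF-beta targets (heterozygous versus wildtype), -0.17 for B cell markers (heterozygous versus wildtype), -0.32 for Macrophage markers (heterozygous versus wildtype), 0.055 for histones (knockout versus heterozygous). At least 10 FPKM in 3 libraries, -0.35 for histones (heterozygous versus wildtype), 0.0739 for histones (knockout versus heterozygous). Without wildtype replicate 2, -0.0329 for histones (heterozygous versus wildtype). Without knockout replicate 3, -0.0107 for Red cell membrane (knockout versus heterozygous). The mean of the ribosomal list (knockout versus wildtype) changed sign, at 0.0292 without wildtype replicate 3 and 0.0322 without the 2 libraries, with camera's direction kept and the call lost. Over single libraries left out, the lists with a changed camera direction ranged from -0.26 to -0.0661 for Late erythroid, knockout versus wildtype, -0.59 to 0.40 for Immediate early, knockout versus wildtype, -0.36 to 0.19 for G1/S, knockout versus wildtype, -0.0864 to 0.33 for Type I interferon, knockout versus wildtype, -0.43 to 1.01 for B cell markers, knockout versus wildtype, -0.0329 to 0.43 for histones, heterozygous versus wildtype, -0.0931 to 0.43 for TGF-beta targets, heterozygous versus wildtype, -0.17 to 1.27 for B cell markers, heterozygous versus wildtype, -0.32 to 0.93 for Macrophage markers, heterozygous versus wildtype, -0.47 to 0.055 for histones, knockout versus heterozygous, -0.0107 to 0.20 for Red cell membrane, knockout versus heterozygous. The cause was not tested. Besides these 21 values, 174 kept camera's direction and lost the call and 290 kept both. Of 2282 named gene values, 180 changed sign, and only the REML weights brought calls among them (27).

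The replicate block gave 0 genes in each comparison and 7, 11 and 12 lists. It spanned all 9 libraries, wildtype included, although wildtype was not taken to pair with either group. The main fit held no pairing, and no fit paired the knockout and heterozygous libraries alone. Every list called at first stayed called with the block (6, 9 and 12), so it removed no call, and it added the macrophage list between knockout and wildtype, and the immediate early and T cell lists between heterozygous and wildtype. The planned edgeR fit on recovered reads was not run. Of simulated changes, with many genes changed at once, 7.6% were called at 1.5-fold, 33.4% at 2-fold and 73.2% at 4-fold. The absence of calls therefore does not exclude changes of these sizes.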

Other observations

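All tests in this part were chosen after the values had been seen, except that of the Mettl7a1 reads. The immediate early list had a mean log2(FPKM + 1) of 5.75 in wildtype replicate 1 and of 3.73 and 3.77 in wildtype replicates 2 and 3. It was 3.79 to 4.59 in heterozygous and 3.98 to 4.56 in knockout libraries. The spread within wildtype thus rests on wildtype replicate 1. Fos, a transcription factor induced within minutes of a stimulus, was at 252 FPKM in wildtype replicate 1 and at 30.8 to 110 FPKM in the other 8 libraries. Ccl3, a chemokine of activated myeloid cells, was at 153 FPKM in wildtype replicate 1 and at most 45.5 FPKM elsewhere. Lars2, the mitochondrial leucyl-tRNA synthetase, was at 458 FPKM in heterozygous replicate 2 and at 23.2 to 91.5 FPKM elsewhere. Apobec3 was at 96.8 and 103 FPKM in replicate 1 of wildtype and heterozygous, and at 6.06 to 9.40 FPKM in the other 7 libraries. Fam118a, on the same chromosome, was at 1.09 and 1.118 FPKM in those 2 libraries and at 3.72 FPKM or more in the others.

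The Y-linked genes were near 0 in the library labelled knockout replicate 2 and expressed in the other 8. Ddx3y was at 0.410 FPKM there and 15.6 FPKM or more elsewhere. Eif2s3y was at 0.599, Uty at 0.202 and Kdm5d at 0 FPKM there, against at least 40.04, 4.98 and 3.62 FPKM elsewhere. Xist and Tsix, also in the fixed list, are not in the deposited table. The labels give no sex. This library belongs to the knockout group, so a difference of sex would enter both knockout comparisons and the allele slope. The adjusted gene counts were 0 with and without it, which cannot exclude an effect of sex, and sex itself was not tested. Without it, limma's count at an unadjusted p below 0.05 went from 43 to 252 between knockout and wildtype. Between knockout and heterozygous it went from 56 to 499. Of the lists called in these comparisons, 1 of 6 and 4 of 12 stayed called in the same direction.

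Markers of other blood cells varied together between libraries. All 9 lineage lists had their lowest mean in wildtype replicate 3, which restates the pattern and would follow from any shared shift, so RNA of such cells in the sorted population cannot be told apart from other causes. Of their 127 tested genes, 8 stand in more than 1 list and 23 were at 10 FPKM or more in that library. S100a9 ran from 101 to 539 FPKM. Whether the CD71+Ter119+ gate held such cells was not tested. Depth stays open: each shallower library lay above each deeper one, and the range within the deeper libraries, 1.74 times the difference between the depth sets (1.02), rests on wildtype replicate 3 (0.41 against 0.70 without it). Genotype stays open too, since the range inside wildtype, 10.04 times the largest difference of genotype means (0.26), rests on the same library (0.45 against 0.55 without it). Dissociation or sorting differences were not tested.

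Mettl7a3, Mettl7a2 and Smarcd1, near Dhh, were among the 4 lowest unadjusted p between knockout and wildtype. Strain variants carried along with the targeted locus are a candidate explanation. Without the 3 genes seen first, the other 80 genes within 5 Mb had a mean absolute t of 0.74. Runs of as many neighbouring genes had a median of 0.52, and 0.74 lay at percentile 99.5 of them. These runs overlap and the region was picked after its genes were seen, so the percentile is no p-value. Mettl7a3 was at 2.10 and 0.758 FPKM in heterozygous replicates 1 and 2 and at 0.0453 FPKM (1 read) in replicate 3, a level near that of wildtype. Mettl7a2+Methig1 was at 1.53 and 0.461 FPKM in heterozygous replicates 1 and 2 and listed at 0 in replicate 3. Smarcd1 (8.935 FPKM), Tuba1a (5.19 FPKM), Cela1 (29.7 FPKM) and Tmem106c (2.645 FPKM) in heterozygous replicate 3 also lay within their wildtype ranges. These were 8.879 to 12.43, 4.56 to 9.99, 20.3 to 42.2 and 1.464 to 3.594 FPKM. Dazap2 did not, at 131 FPKM against 186 to 216 FPKM in wildtype. An effect of Dhh loss itself cannot be told apart from linked DNA, because both would follow the genotype short of a crossover. A wrong label of heterozygous replicate 3 or a crossover there stays untested. Reads shared with Mettl7a1 cannot be told apart either. Its scaled reads changed by -178.9 ± 234.1 (SE) against a gain of 38.9 for Mettl7a3. This met the criterion fixed beforehand, a fall in Mettl7a1 at least as large as the gain. The SE exceeds the fall, so the test cannot decide, and the spread was added to this criterion after the value was seen.

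Other splits of the same libraries were counted. With 10 splits of 6 libraries no share under 0.05 can be reached. For genes the real count was 0 in each comparison, so that 10 of 10 splits in each pair and 100 of 100 drawn for the allele number reach it by construction, and these tallies test nothing. The highest other count was 1730 for knockout versus wildtype, 0 in the other pairs and 2796 for the allele number, where 2 splits gave any gene. The split with 1730 parts wildtype replicates 1 and 2 and knockout replicate 2 from the rest, which are the shallower and deeper libraries of the pair, and it points to a structure of the samples. With depth as a term the real count was 0. For lists, 10, 8 and 2 of 10 splits gave as many as the real 6, 9 and 12, with highest others of 20, 20 and 14. Same-numbered knockout and heterozygous libraries were taken to pair from their correlations alone. The 3 other splits of these groups that part all 3 pairs gave 6, 8 and 10 lists against the real 12. Each swapped the genotype within 1 pair. So few splits cannot reach a share under 0.05 either, and no conclusion is drawn from them.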
